A study of Mus musculus with 8 samples.

How the data were processed

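The series holds RNA sequencing of sorted adult mouse bone marrow cells negative for the blood markers CD45 and TER119. Per the labels, 4 populations were sorted, with 2 libraries each, 8 libraries in all. LepR-cre, NG2-cre and Myh11-creER cells were negative for the endothelial marker CD31 and carried the red Tomato reporter, which a cre recombinase driven by the leptin receptor gene, by Cspg4 (the gene of NG2) or, after tamoxifen, by smooth muscle myosin heavy chain had switched on. The last population was positive for CD31, an endothelial protein. RNA was amplified with a SMART-Seq kit, tagmented with Nextera XT and sequenced on a HiSeq2500. The authors aligned reads with STAR and counted them with featureCounts on build mm10; versions and the gene annotation are not given in the sources used here. The deposited table gives RPKM, that is read counts scaled by gene length and library size, for 24062 genes in the 8 libraries, and the authors do not state which reads define library size.

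Groups were taken from the sample titles, which the column names of the table match. The population labels of the LepR-cre and Myh11-creER samples are exchanged relative to the titles: samples titled Myh11-creER carry a LepR-cre population label and the reverse. Lepr and Myh11 RPKM followed the titles, so the titles were used. The labels do not say whether the 2 libraries of a group came from separate animals, so p-values measure only the spread between these samples. Replicate numbers were not used to pair libraries: across genes, the deviations of libraries with the same number correlated between -0.41 and 0.16 over the 6 pairs of groups.

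In the table, 27 entries carry dates in place of gene symbols, which a spreadsheet makes of the March and Sept gene families, and these were left out (0.24% to 0.32% of the RPKM of a library). Adult globin genes such as Hba-a1 and Hbb-bs are listed at 0 in all 8 libraries, and the table has no mitochondrially encoded genes. RPKM of each gene are whole multiples of a step set by 1 read, so whole reads and library totals were recovered with Python 3.11.15 (NumPy 2.4.6, pandas 2.3.3): all 17883 genes above 0 (100%) gave whole reads within a tolerance of 0.02 reads. The totals came to 56068119 and 49515874 reads for Myh11-creER replicates 1 and 2, 64971514 and 59694476 for NG2-cre, 65354800 and 49207505 for LepR-cre, and 34532355 and 45408978 for CD31. At these depths, a floor of 3 reads in a gene of 2000 bases lay at 0.023 to 0.0434 RPKM, which covers counting error only, since amplified reads are not independent molecules. Between replicates, recovered reads varied far more than counting error: chi-square per degree of freedom was 114 for LepR-cre, 501 for NG2-cre, 419 for Myh11-creER and 61.6 for CD31.

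Genes with an RPKM of at least 1 in at least 2 libraries were kept (12321 genes) and taken as log2(RPKM + 1). One linear model of the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend), with 4 residual and 3.16 prior degrees of freedom. All 4 comparisons, namely LepR-cre against NG2-cre, LepR-cre against Myh11-creER, NG2-cre against Myh11-creER and CD31 against the mean of the 3 stromal groups, were tested two-sided. P-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Of 25 gene lists written before the data were examined, 24 had at least 5 tested members and were tested with limma's camera, which asks whether a list is shifted against all other genes, with a preset correlation of 0.01 between genes and again with an estimated correlation. With the estimate, camera also tests on the 4 residual degrees of freedom, in place of nearly as many as there are genes. It therefore has little power here, and its adjusted p does not show that a list is unchanged. The list of mitochondrially encoded mRNAs had no member in the table and was not tested. Members were also adjusted over the list alone. Lists share members, for example 9 of the 27 tested niche factors and 10 of the 26 markers of CXCL12-abundant reticular (CAR) cells stand in another list. Figures were drawn with matplotlib 3.10.9, and loci come from GENCODE release M21 on mm10.

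Genes to be named were fixed by a rule before the data were examined: Lepr, Cspg4, Myh11 and Pecam1; Cxcl12 and Kitl; up to 8 genes per direction with the largest change, an adjusted p under 0.05, no overlap between the groups, a mean of at least 10 RPKM on the higher side and no placeholder symbol; and for each list past its test, the 4 members with the largest change past the threshold, or without any the 2 with the highest mean RPKM. A gene outside this rule is marked as chosen after its values were seen, once in each paragraph.

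The fit was tested on simulated data with the mean level of each gene over all 8 libraries and 1 distribution of spread for all groups. In it, 200 genes above a minimum level were changed in 1 group. Of 100 genes changed 2-fold, 27, 30, 30 and 55 were called in the 4 comparisons in the order given above, and of 100 changed 4-fold, 81, 82, 84 and 95 were called. False calls numbered 8, 3, 11 and 14 among 12099, 12097, 12098 and 12097 unchanged genes. None of the 23 unchanged lists was called (0 of 23), in data simulated with independent genes. Measured replicates lay further apart in NG2-cre and Myh11-creER (median absolute log2 difference 0.224 and 0.282) than in LepR-cre and CD31 (0.188 and 0.182). The simulated recovery may thus be too favourable for comparisons with NG2-cre or Myh11-creER.

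Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter beyond RPKM above 0, a filter at RPKM of 5 in 2 libraries, median-of-ratios scaling, quantile normalization, robust eBayes, array weights, the replicate number as a block, a test against a 2-fold change, a fit with the 2 compared groups alone, camera with an estimated correlation, and leaving out each library in turn. Added after seeing the data were voom on the recovered reads, a block with the Myh11-creER replicate numbers exchanged, a covariate for Y-linked transcripts, and a fit without Myh11-creER replicate 1 and NG2-cre replicate 2, the libraries with high cartilage transcripts. Leaving out a library also lowers the residual degrees of freedom. Calls can then end through lost power, also where the library belongs to neither compared group. Between LepR-cre and NG2-cre, the Y-linked covariate by construction leaves out NG2-cre replicate 1, and between NG2-cre and Myh11-creER replicate 2. There it repeats those omissions and is no separate check.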

Results

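Expression was measured by RNA sequencing in 4 sorted populations of adult mouse bone marrow, with 2 libraries each: stromal cells traced by LepR-cre, NG2-cre or Myh11-creER, and CD31+ endothelial cells. These are cells that lie in or around marrow vessels, where blood stem cells reside, and the comparisons ask which of them carries which haematopoietic niche factors. Total reads per library ran from 34532355 to 65354800, and 14345 to 15820 genes per library were above 0. Values are deposited RPKM with the mean and SD of 2 libraries, and log2 fold changes of RPKM + 1 carry the SE of the limma fit.

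The genes of the sort and the cre drivers set the Myh11-creER and CD31 libraries apart, but no such gene passed the threshold between LepR-cre and NG2-cre. Lepr, the leptin receptor (chromosome 4, 101717404 to 101815352), was at 1600 ± 47.7 RPKM (SD, n = 2) in LepR-cre, 1130 ± 157 in NG2-cre, 321 ± 95.1 in Myh11-creER and 19.9 ± 10.7 in CD31 libraries. Myh11, smooth muscle myosin heavy chain (chromosome 16, 14194535 to 14291372), was at 551 ± 210 in Myh11-creER, 31.7 ± 12.7 in NG2-cre, 1.56 ± 0.531 in LepR-cre and 0.353 ± 0.0548 in CD31. Cspg4, which encodes NG2 (chromosome 9, 56865033 to 56899870), was highest not in NG2-cre cells (11.1 ± 8.14) but in Myh11-creER cells (170 ± 25.3), and stood at 0.27 ± 0.0106 in LepR-cre. Pecam1, which encodes CD31 (chromosome 11, 106654217 to 106750628), was at 424 ± 22.9 in CD31 libraries and at 0.135 to 4.24 in the 6 stromal libraries. Lepr and Myh11 thus followed the sample titles and not the population labels, which are exchanged between LepR-cre and Myh11-creER.

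**Figure D1:**
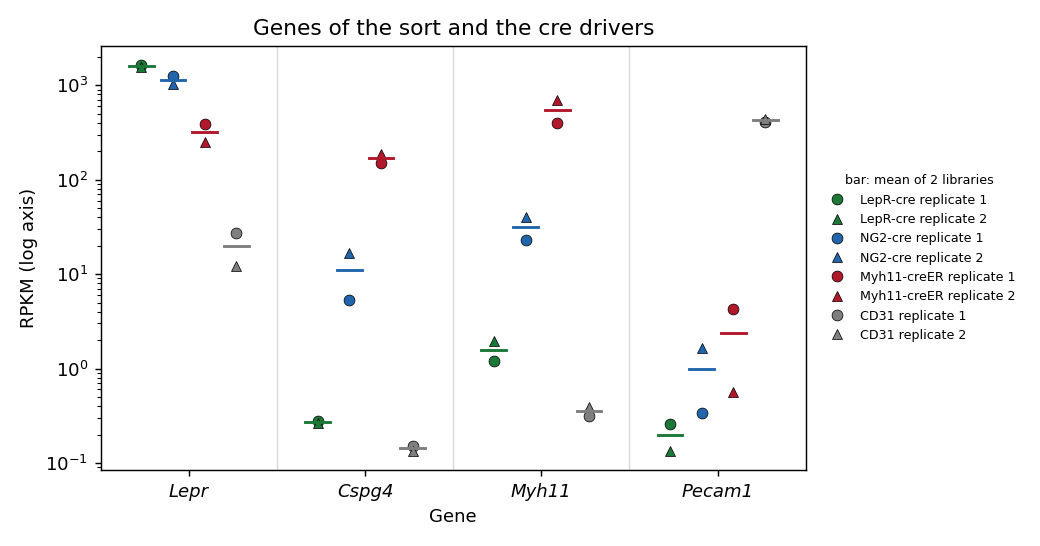
RPKM (log axis) of Lepr, Cspg4, Myh11 and Pecam1 in each of the 8 libraries, coloured by group, with bars at the mean of 2 libraries. Lepr was highest in LepR-cre (1600), Cspg4 (170) and Myh11 (551) in Myh11-creER, and Pecam1 (424) in CD31 libraries.

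Component 1, with 63.5% of the variance, set the CD31 libraries (119.6 and 128.5) apart from the stromal ones (-55.2 to -17.6). On component 2, with 25%, the Myh11-creER libraries stood at 80.9 and 70.3, and NG2-cre replicate 1 (-36.1) lay beside LepR-cre (-45.7 and -37.7) and away from NG2-cre replicate 2 (-3.5). Across genes, log2 values correlated between replicates at 0.983 for LepR-cre and CD31, 0.959 for NG2-cre and 0.935 for Myh11-creER. NG2-cre replicate 1 correlated with the LepR-cre libraries at 0.976 and 0.974, above its correlation of 0.959 with NG2-cre replicate 2. Transcripts of other cells differed between libraries of 1 group. Col2a1, the main cartilage collagen, was at 2110 RPKM in Myh11-creER replicate 1 and 1.53 in replicate 2, and at 950 in NG2-cre replicate 2 and 9.79 in replicate 1. S100a8, a granulocyte transcript, was at 5980 and 1530 in Myh11-creER, 49.2 and 724 in NG2-cre, 208 and 322 in LepR-cre, and 1830 and 744 in CD31, although CD45+ cells were excluded by the sort. Ddx3y, a Y-linked gene, was at 24.6 and 27.3 in Myh11-creER, 26.1 and 28.4 in CD31 and 21.3 in NG2-cre replicate 1, and was listed at 0 in NG2-cre replicate 2 and both LepR-cre libraries. The Col2a1, S100a8 and Ddx3y values were chosen after they were seen.

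**Figure D2:**
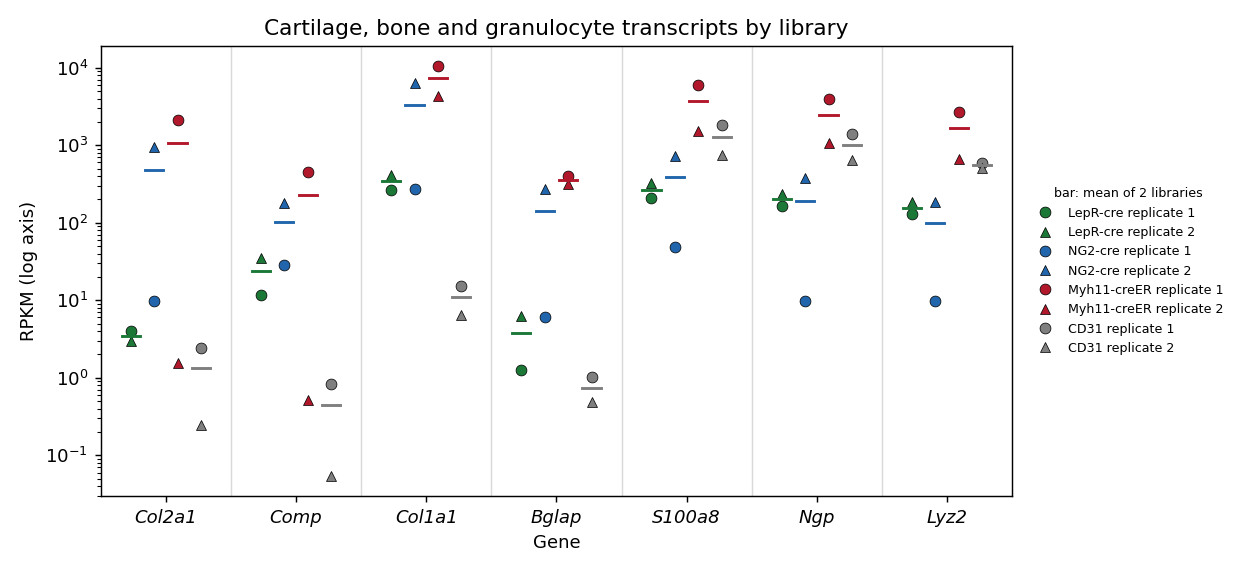
RPKM (log axis) of cartilage (Col2a1, Comp), bone (Col1a1, Bglap) and granulocyte (S100a8, Ngp, Lyz2) transcripts in each of the 8 libraries, coloured by group, with bars at the mean of 2 libraries. Col2a1 lies at 2110 in Myh11-creER replicate 1 and 950 in NG2-cre replicate 2, and under 10 in the other 6 libraries.

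LepR-cre cells carried more of the main haematopoietic niche factors than Myh11-creER cells. Cxcl12, the chemokine that retains blood stem cells in marrow (chromosome 6, 117168535 to 117181367), was at 10400 ± 152 RPKM (SD, n = 2) against 1760 ± 291, a log2 fold change of 2.57 ± 0.47 (SE, adjusted p = 0.00811). Kitl, stem cell factor (chromosome 10, 100015630 to 100100416), was at 386 ± 92 against 80.8 ± 3.77, a log2 fold change of 2.22 ± 0.24 (SE, adjusted p = 0.000961). Bmp4, a bone morphogenetic protein, was higher by 3.56 ± 0.15 (SE, adjusted p = 0.000212), and Il7, the cytokine of early B cells, by 2.66 ± 0.45 (adjusted p = 0.0057). Of 27 niche factors tested, 13 were higher, 6 lower and 8 not past the threshold, and 14 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.000502; adjusted p = 0.608 with an estimated correlation). The 6 lower members were Il6, an inflammatory cytokine (log2 fold change -2.95, adjusted p = 0.00265), and Pdgfa (-2.36), Cxcl1 (-2.16), the Notch ligands Jag1 (-2.01) and Dll1 (-0.99), and Tgfb1 (-1.50). All of these but Il6, and Csf1 (2.16), Vcam1 (1.98) and Angpt1 (1.52) among the higher members, were chosen after their values were seen. Leaving out 1 library ended single calls of Cxcl12 (adjusted p = 0.0535 without LepR-cre replicate 1 and 0.0536 without replicate 2), Pdgfa (0.0511 without LepR-cre replicate 1) and Jag1 (0.063 without LepR-cre replicate 2). The call of Cxcl1 ended without LepR-cre replicate 1 (0.0664) or 2 (0.0952) or Myh11-creER replicate 2 (0.0588), and that of Tgfb1 ended without 4 of the libraries, with a highest value of 0.121 without LepR-cre replicate 1. That of Dll1 ended without any library but Myh11-creER replicate 1, with a highest value of 0.204 without LepR-cre replicate 1. Without LepR-cre replicate 1, 2 niche factors were lower, and without replicate 2, 3. With a pseudocount of 0.1 the adjusted p of Il7 was 0.0615. A covariate for Y-linked transcripts ended the calls of Cxcl12 (log2 fold change 3.21, adjusted p = 0.055), Il6 (-1.79, 0.076) and Il7 (2.32, 0.127). That covariate rests on NG2-cre replicate 1 against 2, which also differ in cartilage, bone and granulocyte transcripts.

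**Figure D3:**
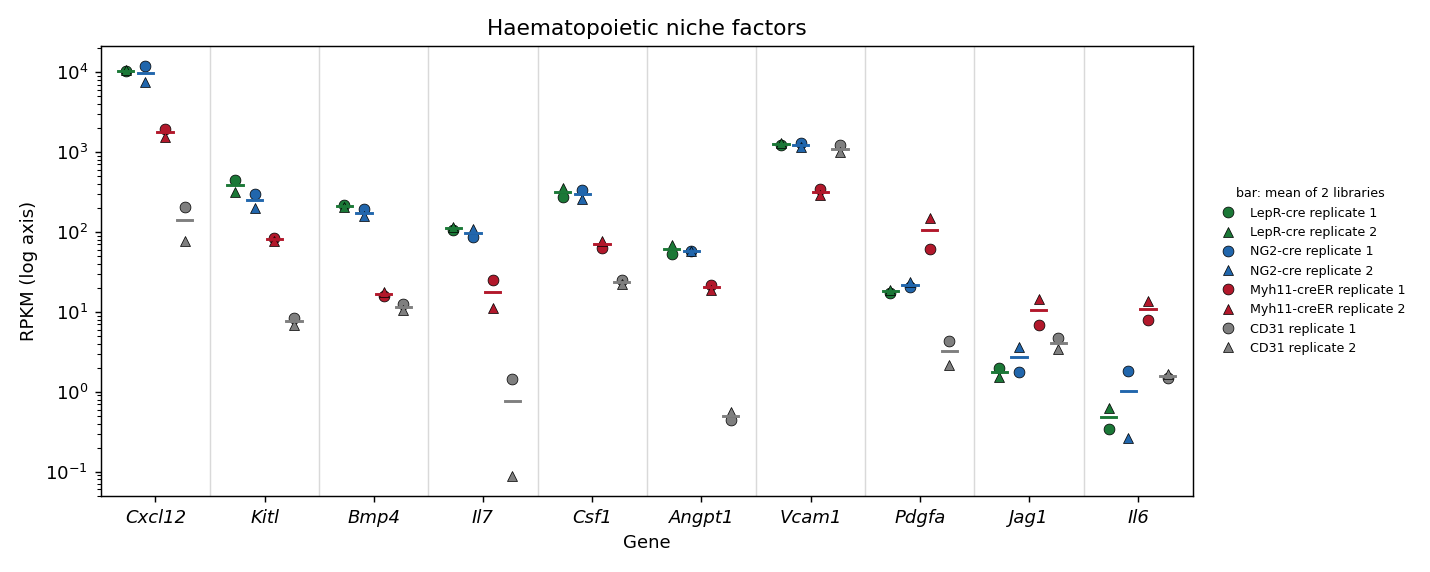
RPKM (log axis) of 10 haematopoietic niche factors in each of the 8 libraries, coloured by group, with bars at the mean of 2 libraries. Mean Cxcl12 was 10400 in LepR-cre, 9650 in NG2-cre, 1760 in Myh11-creER and 142 in CD31 libraries, while Il6, Jag1 and Pdgfa had their highest means in Myh11-creER.

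Markers of CAR cells, the reticular cells that make most Cxcl12 in marrow, were higher in LepR-cre than in Myh11-creER cells in 22 of 26 genes, with none lower (0) and 4 not past the threshold. Adjusted over the list alone, 23 were higher and 1 lower (camera adjusted p = 1.08e-14; adjusted p = 0.608 with an estimated correlation). Examples were the chemokine Cxcl14 (log2 fold change 3.31 ± 0.49, adjusted p = 0.00337), the endothelial cell-specific molecule Esm1 (2.73 ± 0.36, 0.00228), and the adipokine Adipoq (2.98 ± 0.56, 0.00897). Without LepR-cre replicate 2, 14 of the 26 were higher. The call of Adipoq ended without LepR-cre replicate 1 or 2 (adjusted p = 0.0577 for each), and with the Y-linked covariate (log2 fold change 2.50, 0.168). Among the genes with the largest differences, Rspo2, an amplifier of Wnt signalling, was higher by 3.92 ± 0.31 (adjusted p = 0.000356), the TGF-beta binding protein Ltbp2 by 3.49 ± 0.53 (0.00382; 2.80 and 0.112 with the Y-linked covariate), and the laminin chain Lama1 by 3.44 ± 0.28 (0.000377). Serpina3n, a protease inhibitor, was higher by 6.58 ± 1.75 (0.0324), but its call ended without 1 of 5 libraries, with a highest adjusted p of 0.138 without LepR-cre replicate 2.

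Contractile genes of smooth muscle were lower in LepR-cre than in Myh11-creER cells in 23 of 24 genes, with 1 not past the threshold and 23 lower when adjusted over the list alone (camera adjusted p = 9.55e-15; adjusted p = 0.608 with an estimated correlation). Acta2, smooth muscle actin, was at 2.56 ± 1.32 RPKM (SD, n = 2) against 3580 ± 1760, a log2 fold change of -9.93 ± 0.47 (SE, adjusted p = 0.000212), and Myh11 differed by -7.71 ± 0.34 (0.000212). Pericyte markers were lower in 18 of 20 genes, and in 19 when adjusted over the list alone (camera adjusted p = 1.1e-12; adjusted p = 0.608 with an estimated correlation). Among them were the regulator of G protein signalling Rgs5 (-7.71 ± 0.55), the gap junction gene Gja4 (-7.89 ± 0.47), the adhesion molecule Mcam (-7.57 ± 0.54) and Cspg4 (-7.06 ± 0.43). Outside these lists, Sncg, gamma-synuclein (-8.63 ± 0.53), and the adhesion molecule Esam (-7.76 ± 0.42) were also lower, with adjusted p = 0.000219 each. All of these genes kept their calls without each library in turn.

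Immediate-early and stress genes were lower in LepR-cre than in Myh11-creER cells in 16 of 23 genes, and 16 lower with 1 higher when adjusted over the list alone (camera adjusted p = 4.2e-05; adjusted p = 0.961 with an estimated correlation). Among them were the transcription factors Atf3 (log2 fold change -4.35 ± 0.4) and Nr4a1 (-4.16 ± 0.28). Nucleus-encoded genes of oxidative phosphorylation were lower in 19 and higher in 1 of 29, and 25 lower with 1 higher when adjusted over the list alone (camera adjusted p = 1.15e-05; adjusted p = 0.961 with an estimated correlation). Atp5b of the ATP synthase differed by -1.13 ± 0.19, and 12 genes of the list were lower after median-of-ratios scaling. Counts of lower genes moved with single libraries: immediate-early genes to 10 without LepR-cre replicate 1, and oxidative phosphorylation genes to 7 and 4 without LepR-cre replicates 1 and 2 and to 9 without Myh11-creER replicate 2, with the 1 higher gene lost without any 1 of the LepR-cre or CD31 libraries or Myh11-creER replicate 2. Without either NG2-cre library 1 immediate-early gene was higher. Cell cycle genes were lower in 9 of 24, and in 16 when adjusted over the list alone (camera adjusted p = 0.000502; adjusted p = 0.961 with an estimated correlation). Their member with the largest difference, Top2a (topoisomerase II), was at 24.6 and 3.54 RPKM in Myh11-creER replicates 1 and 2 and at 0.349 and 0.915 in LepR-cre. Leukocyte genes were lower in 5 of 22, and in 13 when adjusted over the list alone (camera adjusted p = 0.00258; adjusted p = 0.961 with an estimated correlation). S100a8, granulocyte Ngp (3910 and 1070 in Myh11-creER against 165 and 235) and the blood cell marker Ptprc (20.1 and 5.37 against 0.227 and 0.99) moved with these lists, and all were highest in Myh11-creER replicate 1. Without that replicate the leukocyte list was no longer called (adjusted p = 0.219) and Top2a stood at -1.5 (adjusted p = 0.0828, from -2.75 and 0.0381). The call of Top2a also ended without either CD31 or either LepR-cre library, with a highest adjusted p of 0.171 without LepR-cre replicate 1, and with the Y-linked covariate (-3.77, 0.129). Cytosolic ribosomal protein genes were lower in 4 of 35, with 0 when adjusted over the list alone (camera adjusted p = 0.0213; adjusted p = 0.961 with an estimated correlation). The call ended without Myh11-creER replicate 1 (0.219), without LepR-cre replicate 2 (0.68), without both libraries high in cartilage transcripts (0.0979) and after median-of-ratios scaling (0.118). No cell cycle (0), leukocyte (0) or ribosomal protein gene (0) was past the threshold in limma without LepR-cre replicate 1 or 2. Without Myh11-creER replicate 1 these counts were 3, 0 and 0, without replicate 2 they were 23, 14 and 1, and without either CD31 library 3, 2 and 0. Leukocyte genes numbered 13 without either NG2-cre library. Ngp and Ptprc values were chosen after they were seen, as were the S100a8 values.

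In all, 1135 genes were higher and 2110 lower in LepR-cre than in Myh11-creER cells, and 697 and 1385 of them by over 2-fold. The libraries of the compared groups did not overlap in 66% of genes, where chance gives 33.3%. The other 15 lists were not called. Counts higher and lower were 3 and 7 of 22 for osteolineage genes (3 and 8 when adjusted over the list alone), 3 and 5 of 15 for adipocyte lineage genes and 2 and 6 of 21 for fibroblast matrix genes. They were 2 and 7 of 16 for basement membrane genes (3 and 9 when adjusted over the list alone), 1 and 8 of 18 for Notch pathway genes (2 and 9 over the list alone), 4 and 5 of 14 for neuropeptide, adrenergic and leptin receptors, and 0 and 2 of 20 for chondrocyte genes. Among vessel lists they were 2 and 7 of 23 for pan-endothelial, 2 and 6 of 17 for arterial, and 5 and 2 of 17 for sinusoidal and venous genes. The remaining counts were 0 and 2 of 20 for interferon-stimulated, 1 and 2 of 9 for Schwann cell, 0 and 0 of 11 for erythroid, 0 and 1 of 12 for megakaryocyte, and 1 and 3 of 5 for Y-linked genes with Xist. Adjusted p of these lists ran from 0.132 (pan-endothelial) to 0.903 (interferon-stimulated). Some of these lists were called under other settings. Chondrocyte (1.98e-05), erythroid (0.00036) and pan-endothelial genes (0.00755) were lower without Myh11-creER replicate 2, and sinusoidal genes higher without replicate 1 (0.0289) or without both libraries high in cartilage transcripts (0.0276). Y-linked genes with Xist were lower without NG2-cre replicate 1 (0.0247) or 2 (0.0212). Chondrocyte genes were lower after median-of-ratios (0.0271) or quantile scaling (0.00482), and pan-endothelial genes after median-of-ratios scaling (0.0271) or with a pseudocount of 0.1 (0.0175). With the Y-linked covariate, chondrocyte (0.000459), fibroblast matrix (0.00287), pan-endothelial (0.00834) and osteolineage genes (0.0477) were lower. Counts of these lists also moved when single libraries were left out, which by itself lowers the power of the fit. Without LepR-cre replicate 1, lower genes numbered 1 for osteolineage, 2 for fibroblast matrix, 4 for basement membrane, 4 for Notch pathway and 1 for Schwann cell genes, and 0 for chondrocyte, megakaryocyte and Y-linked genes with Xist. Without replicate 2 they were 2, 3, 4, 4 and 1, and 0 for the same 3 lists, with 1 adipocyte lineage gene higher and 1 interferon-stimulated gene lower. Without Myh11-creER replicate 1, 2 osteolineage, 3 fibroblast matrix, 0 chondrocyte, 1 Y-linked and 4 interferon-stimulated genes were lower and 1 chondrocyte gene higher. Without Myh11-creER replicate 2, 13 chondrocyte, 7 erythroid, 6 sinusoidal, 4 Schwann cell, 3 megakaryocyte and 0 Y-linked genes were lower. Without either CD31 library, 4 osteolineage, 3 fibroblast matrix, 0 chondrocyte and 1 Y-linked gene were lower. Without either NG2-cre library 1 interferon-stimulated gene was higher, and the 1 higher member of the Y-linked list was lost without any 1 of the other 6 libraries. Sinusoidal and interferon-stimulated lists had negative medians (-0.18 and -0.22) and means (-0.28 and -0.38) where the test against other genes pointed up (adjusted p = 0.309 and 0.903). The median log2 fold change over all genes was -0.186, and scaling moved it to -0.017 (median of ratios) or 0.106 (quantile). The share of higher genes among the calls went from 35% to 50.8% or 59.4%, and to 37.2% with voom, while each of the 9 called lists kept its direction. Without LepR-cre replicate 1 the counts fell to 555 and 918, and without replicate 2 to 529 and 1018. Y-linked transcripts were present in both Myh11-creER and absent from both LepR-cre libraries, so that for single genes of this comparison sex and population cannot be told apart. Tamoxifen is named for Myh11-creER alone, so it also cannot be told apart from population in any comparison with that group. Its effect was not tested. For the pattern as a whole, values speak against sex as the only source. NG2-cre replicate 1 had Ddx3y, chosen after its values were seen, at 21.3 RPKM. This library correlated with the LepR-cre libraries at 0.976 and 0.974 and with the Myh11-creER libraries at 0.823 and 0.863. Without NG2-cre replicate 2, where Ddx3y is listed at 0, the comparison of NG2-cre with Myh11-creER had 622 genes higher and 1271 lower. With the Y-linked covariate LepR-cre against Myh11-creER had 430 and 903, of which 1174 were shared in direction with the calls above.

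**Figure D4:**
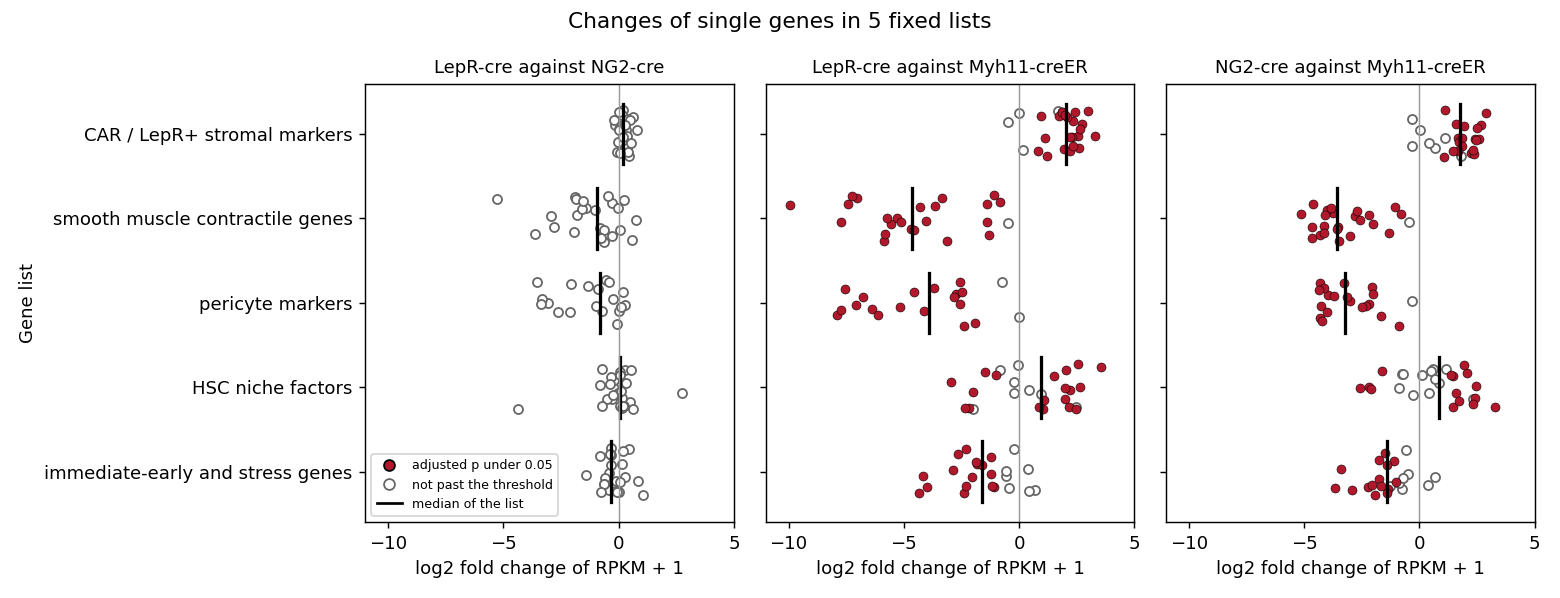
Log2 fold changes of RPKM + 1 for single genes (points) of 5 fixed lists in the 3 comparisons between stromal groups, filled where the adjusted p is under 0.05, with a black bar at the median of each list. Of the CAR markers, 22 of 26 were higher in LepR-cre and 19 of 26 in NG2-cre than in Myh11-creER cells, and none of the points (0) of LepR-cre against NG2-cre is filled.

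NG2-cre cells, compared with the same 2 Myh11-creER libraries, had more of several niche factors and CAR markers and less of the contractile and pericyte genes. Cxcl12 was at 9650 ± 3020 RPKM (SD, n = 2) in NG2-cre, higher by a log2 fold change of 2.43 ± 0.47 (SE, adjusted p = 0.0131), and Kitl was at 251 ± 69.4, higher by 1.59 ± 0.24 (adjusted p = 0.00506). Bmp4 was higher by 3.29 ± 0.15 (adjusted p = 0.00102) and Il7 by 2.47 ± 0.45 (0.0101), while Il6 was lower (-2.60 ± 0.41, 0.00602). Of 27 niche factors, 11 were higher and 4 lower, and 14 and 5 when adjusted over the list alone (camera adjusted p = 1.26e-05; adjusted p = 0.624 with an estimated correlation). CAR markers were higher in 19 of 26 genes, and in 22 when adjusted over the list alone (camera adjusted p = 1.6e-14; adjusted p = 0.624 with an estimated correlation). They included Cxcl14 (2.90 ± 0.49) and the BMP antagonist Grem1 (2.58 ± 0.43). Largest differences included the complement component C6 (4.12 ± 0.44), Rspo2 (3.73 ± 0.31), the Wnt inhibitor Wif1 (3.42 ± 0.49) and the angiopoietin Angpt4 (3.25 ± 0.34), with adjusted p from 0.00131 for Rspo2 to 0.00429 for Wif1. Without NG2-cre replicate 1, 10 CAR markers were higher, and without it or Myh11-creER replicate 2, 2 niche factors were lower. The call of Cxcl12 ended without NG2-cre replicate 1 (adjusted p = 0.0718) or Myh11-creER replicate 2 (0.0504), and those of Il7 (0.0875) and Wif1 (0.0762) ended with a pseudocount of 0.1.

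Contractile genes were lower in NG2-cre than in Myh11-creER cells in 23 of 24 genes, over all genes and when adjusted over the list alone (camera adjusted p = 2.17e-14; adjusted p = 0.643 with an estimated correlation). Pericyte markers were lower in 19 of 20, on both adjustments (camera adjusted p = 6.11e-12; adjusted p = 0.643 with an estimated correlation). Examples were Casq2, calsequestrin (log2 fold change -5.16 ± 0.3, adjusted p = 0.00113), Acta2 (-4.65 ± 0.47, 0.00166), Rgs5 (-4.34 ± 0.55, 0.00293) and the potassium channel Kcnj8 (-4.30 ± 0.5, 0.00229). Acta2 stood at 89.9 and 197 RPKM in the NG2-cre libraries, against 2330 and 4830 in Myh11-creER and 3.49 and 1.63 in LepR-cre. Immediate-early and stress genes were lower in 15 of 23, and 18 lower with 1 higher when adjusted over the list alone (camera adjusted p = 1.27e-05; adjusted p = 0.863 with an estimated correlation). Examples were Btg2 (-3.65 ± 0.3) and Nr4a1 (-3.41 ± 0.28). Oxidative phosphorylation genes were lower in 13 and higher in 1 of 29, and 26 lower with 1 higher when adjusted over the list alone (camera adjusted p = 1.62e-05; adjusted p = 0.863 with an estimated correlation). Uqcrfs1 of complex III differed by -0.99 ± 0.15, and 6 genes of the list were lower after median-of-ratios scaling. Its count of lower genes was 2 without NG2-cre replicate 1, 24 and 5 without Myh11-creER replicates 1 and 2, and 7 without any 1 of the LepR-cre or CD31 libraries, and its 1 higher gene was lost without each library in turn. Without NG2-cre replicate 2, 9 immediate-early genes were lower and 1 higher.

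Leukocyte genes were lower in NG2-cre than in Myh11-creER cells in 11 of 22, and in 17 when adjusted over the list alone (camera adjusted p = 0.000101; adjusted p = 0.863 with an estimated correlation). This moved with single libraries. Lyz2, lysozyme of myeloid cells, was at 9.67 and 187 RPKM in NG2-cre replicates 1 and 2 against 2650 and 656 in Myh11-creER. Its log2 fold change of -4.88 (adjusted p = 0.0326) went to -2.81 without NG2-cre replicate 1 (0.0746) and to -3.87 without Myh11-creER replicate 1 (0.116). Its call also ended without any CD31 or LepR-cre library, with 0.0752 as the highest of these. Cell cycle genes were lower in 5 of 24, and in 6 when adjusted over the list alone (camera adjusted p = 0.000584; adjusted p = 0.895 with an estimated correlation). The call ended without Myh11-creER replicate 1 (0.112). In limma, 0 leukocyte genes were past the threshold without NG2-cre replicate 1 or Myh11-creER replicate 1 and 3 without any 1 of the LepR-cre or CD31 libraries. For cell cycle genes the count was 0 without NG2-cre replicate 1 or 2, 1 without Myh11-creER replicate 1 or any 1 of the LepR-cre or CD31 libraries, and 23 without Myh11-creER replicate 2. Osteolineage genes were higher in 6 of 22, on both adjustments (camera adjusted p = 0.00244; adjusted p = 0.863 with an estimated correlation). Among them were Phex, a regulator of bone mineral (1.89 ± 0.3, adjusted p = 0.00619), and the cadherin Cdh11 (1.97 ± 0.38, 0.0131; 0.0778 without NG2-cre replicate 1). That list moved with NG2-cre replicate 2, where the bone collagen Col1a1 was at 6280 RPKM against 269 in replicate 1. It was not called without replicate 2 (0.357), after quantile normalization (0.114) or without both libraries high in cartilage transcripts (0.0773). Without NG2-cre replicate 1 or Myh11-creER replicate 2, 3 osteolineage genes were higher, and without NG2-cre replicate 2, 6 were lower. Sinusoidal and venous genes were higher in 5 and lower in 2 of 17, and 7 and 2 when adjusted over the list alone (camera adjusted p = 0.00309; adjusted p = 0.863 with an estimated correlation). Its members went both ways, with the chemokine receptor Ackr3 lower (-3.62 ± 0.62) and the protease Adamts5 (2.29 ± 0.22) and Vcam1 (1.94 ± 0.21) higher. The call ended without NG2-cre replicate 2 (0.0879, 3 higher) or Myh11-creER replicate 2 (0.251, 2 higher), and 3 were higher without CD31 replicate 1 or 2. Interferon-stimulated genes were lower in 3 and higher in 1 of 20, on both adjustments (camera adjusted p = 0.0403; adjusted p = 0.895 with an estimated correlation), with Rsad2 at -3.47 ± 0.41. The call ended without NG2-cre replicate 2 (0.214) or Myh11-creER replicate 2 (0.515). Lower genes numbered 1 without NG2-cre replicate 1 and 8 without Myh11-creER replicate 1, and the 1 higher gene was lost without any library but NG2-cre replicate 1. The Y-linked covariate by construction leaves NG2-cre replicate 2 out of this comparison, so it is no separate check. With it the calls also ended of osteolineage (0.356), interferon-stimulated (0.215) and sinusoidal genes (0.0902). The Col1a1 values were chosen after they were seen.

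In all, 846 genes were higher and 1698 lower in NG2-cre than in Myh11-creER cells, and 535 and 1125 of them by over 2-fold. Here too tamoxifen and population cannot be told apart. Libraries of the compared groups did not overlap in 62.7% of genes, where chance gives 33.3%. The other 13 lists were not called, with adjusted p from 0.0612 (ribosomal protein genes) to 0.944 (the receptor list). Counts higher and lower were 3 and 5 of 15 for adipocyte lineage, 2 and 4 of 17 for arterial, 2 and 7 of 16 for basement membrane, 1 and 5 of 18 for Notch pathway, 2 and 5 of 21 for fibroblast matrix and 2 and 6 of 23 for pan-endothelial genes. They were 4 and 5 of 14 for the receptors, 1 and 2 of 9 for Schwann cell, 0 and 1 of 20 for chondrocyte, 0 and 1 of 12 for megakaryocyte, 0 and 1 of 35 for ribosomal protein, 0 and 0 of 11 for erythroid and 0 and 0 of 5 for Y-linked genes with Xist. Adjusted over the list alone, 2 Notch pathway genes were higher and 8 lower. These counts also moved when single libraries were left out, and part of this may be lost power. The receptors had 0 higher and 2 lower without NG2-cre replicate 1. In the same fit 4 fibroblast matrix, 3 Schwann cell, 1 basement membrane and 1 Y-linked gene were higher, and 4 Y-linked, 3 adipocyte lineage, 3 Notch pathway, 2 fibroblast matrix, 1 Schwann cell and 0 chondrocyte, megakaryocyte and ribosomal protein genes lower. Without NG2-cre replicate 2, 2 receptors, 2 Notch pathway genes and 1 basement membrane gene were higher, and 3 Notch pathway, 3 chondrocyte, 3 ribosomal protein, 1 Y-linked and 0 megakaryocyte genes lower. Without Myh11-creER replicate 1, 4 pan-endothelial and 2 chondrocyte genes were higher, and 3 adipocyte lineage, 3 fibroblast matrix and 0 chondrocyte, megakaryocyte and ribosomal protein genes lower. Without Myh11-creER replicate 2, 0 receptors, 1 adipocyte lineage and 1 basement membrane gene were higher, and 5 erythroid, 3 fibroblast matrix, 3 Notch pathway, 2 chondrocyte, 2 megakaryocyte, 1 Schwann cell and 0 ribosomal protein genes lower. Without any 1 of the LepR-cre or CD31 libraries, 1 basement membrane gene was higher, and 3 adipocyte lineage, 2 fibroblast matrix, 1 Schwann cell and 0 chondrocyte and ribosomal protein genes lower, and without either LepR-cre library 3 Notch pathway genes were lower. Ribosomal protein genes were called lower without NG2-cre replicate 2 (0.000401) or either LepR-cre library (0.0242 and 0.0243), with the Y-linked covariate (0.000415), no filter (0.0165), voom (0.0426) or a pseudocount of 0.1 (0.0481), and without both libraries high in cartilage transcripts (0.0187). Y-linked genes with Xist were called lower without NG2-cre replicate 1 (0.0033), and Schwann cell genes higher with no filter (0.0137). Chondrocyte genes stood on either side according to the library left out: lower without Myh11-creER replicate 2 (adjusted p = 0.00166), and higher without Myh11-creER replicate 1 (0.000369) or NG2-cre replicate 1 (0.0386), with a median of -0.80 and a test that pointed up at 0.926 (down after median-of-ratios or quantile scaling). Erythroid genes did the same, lower without Myh11-creER replicate 2 (0.000424) and higher without replicate 1 (0.0276). Signs of median, mean and test also differed for fibroblast matrix (-0.04, -0.28, up), pan-endothelial (-0.02, -0.29, up), megakaryocyte (0.04, -0.22, up), Schwann cell (0.20, -0.07, up) and receptor genes (-0.31, -0.45, up). The tests of fibroblast matrix, pan-endothelial, megakaryocyte and receptor genes pointed down after median-of-ratios scaling. The median over all genes was -0.182, and went to -0.01 with median-of-ratios scaling or 0.071 with quantile normalization. The share of higher genes among the calls went from 33.3% to 51% or 57.8%, and to 35.4% with voom, while each of the 11 called lists kept its direction. Without NG2-cre replicate 1 the counts fell to 395 and 726.

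No single gene differed past the threshold between LepR-cre and NG2-cre cells. Cxcl12 was at 10400 ± 152 against 9650 ± 3020 RPKM (SD, n = 2; log2 fold change 0.14 ± 0.47, SE), and its sign turned without NG2-cre replicate 2 (-0.18). Kitl was at 386 ± 92 against 251 ± 69.4 (0.63 ± 0.24, adjusted p = 0.918). Limma called 0 genes higher and 0 lower, with 609 genes at an unadjusted p under 0.05, and voom also called 0 and 0. Libraries did not overlap in 32.1% of genes, where chance gives 33.3%. The smallest adjusted p was 0.0662, for 5 genes chosen after their values were seen: Acta2 (-5.29), Myh11 (-3.63), the carboxylesterase Ces1g (1.75), the mitochondrial transhydrogenase Nnt (-1.63) and the protease Adamdec1 (1.67). Spp1, osteopontin, a member of the niche factor list also chosen after its values were seen, was at 188 and 107 RPKM in LepR-cre and at 3600 and 2350 in NG2-cre (-4.35, adjusted p = 0.243). In the simulated data 81 of 100 changes of 4-fold were called in this comparison. There, however, 200 changed genes and a changed contractile list were planted, which eases the adjustment. The simulation also gave every group the same spread, so the lack of calls here does not show equal levels. Without NG2-cre replicate 1, 2 genes were higher and 44 lower. The lower ones included Acta2 (-5.85, adjusted p = 0.0222), Myh11 (-4.04, 0.023), Rgs5 (-4.28, 0.0222), Esam (-3.99, 0.0222) and Cspg4 (-3.82, 0.0202). Without NG2-cre replicate 2, 0 were higher and 2 lower.

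At the preset correlation of 0.01 between genes, 14 of 24 gene lists were called between LepR-cre and NG2-cre cells. With an estimated correlation 0 were called. The estimates were 0.748 for contractile, 0.575 for pericyte, 0.363 for osteolineage, 0.348 for pan-endothelial and 0.536 for interferon-stimulated genes, above the preset. Calls at the preset thus treat genes that vary together as nearly independent, and do not settle whether these lists separate the groups. The test with an estimate does not settle it either, as it also runs on 4 residual degrees of freedom. It did not call pan-endothelial genes in CD31+ cells, where 23 of 23 were higher (camera adjusted p = 0.267). Contractile genes were lower in LepR-cre, with 0 of 24 past the threshold over all genes and 15 lower with 1 higher when adjusted over the list alone (median log2 fold change -0.93, camera adjusted p = 1.65e-15; adjusted p = 0.458 with an estimated correlation). Pericyte markers were lower with 0 of 20 and, adjusted over the list alone, 11 genes (median -0.82, camera adjusted p = 3.56e-13; adjusted p = 0.458 with an estimated correlation), with Rgs5 at 6.49 against 91.7 RPKM. Osteolineage genes were lower with 0 of 22 and, adjusted over the list alone, 4 genes (median -1.25, camera adjusted p = 1.18e-13; adjusted p = 0.458 with an estimated correlation). Pan-endothelial genes were lower with 0 of 23 and, adjusted over the list alone, 6 genes (median -0.50, camera adjusted p = 6.42e-09; adjusted p = 0.458 with an estimated correlation), with Esam at 0.179 against 12.2 RPKM. Interferon-stimulated genes were higher, with 18 of 20 positive and 0 past the threshold on either adjustment, over all genes or adjusted over the list alone (median 0.40, camera adjusted p = 1.1e-06; adjusted p = 0.518 with an estimated correlation). Among them was Irf7, a regulator of interferon genes, at 83.1 against 48.2 RPKM. These 5 lists were called without each library in turn. In the osteolineage list, Col1a1 turned to a log2 fold change of 0.31 without NG2-cre replicate 2. In that library 6 of the 22 osteolineage genes were at least 4 times higher than in NG2-cre replicate 1. Without NG2-cre replicate 1, 3 contractile, 6 pericyte, 4 osteolineage and 2 pan-endothelial genes were lower over all genes.

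The other 9 calls between LepR-cre and NG2-cre cells had 0 genes past the threshold over all genes and each ended without 1 or more libraries. CAR markers were higher with 22 of 26 positive and a median of 0.19 (camera adjusted p = 0.00517; adjusted p = 0.518 with an estimated correlation), but not without NG2-cre replicate 2 (0.431) or LepR-cre replicate 2 (0.0769). Chondrocyte genes were lower (median -2.41, camera adjusted p = 0.000354; adjusted p = 0.64 with an estimated correlation) and turned without NG2-cre replicate 2 (higher, 0.917), the library with Col2a1 at 950 RPKM. Fibroblast matrix genes (lower, 0.035; adjusted p = 0.64 with an estimated correlation) also turned without that library (higher, 0.248). Without it the calls also ended of adipocyte lineage (lower, 0.0437 to 0.87; adjusted p = 0.518 with an estimated correlation) and arterial (lower, 0.035 to 0.248; adjusted p = 0.458 with an estimated correlation). The same held for Schwann cell (lower, 0.00484 to 0.387, or 0.462 with an estimated correlation) and sinusoidal genes (lower, 0.00497 to 0.248, or 0.518 with an estimated correlation). Of these lists, 1 of 9 Schwann cell and 6 of 17 sinusoidal genes reached 1 RPKM in both LepR-cre libraries. Without LepR-cre replicate 2 the calls ended of arterial (0.118), Schwann cell (0.06), sinusoidal (0.0834) and fibroblast matrix genes (0.06), and without LepR-cre replicate 1 those of adipocyte lineage (0.352) and fibroblast matrix genes (0.164). Without CD31 replicate 1 or 2, adipocyte lineage (0.0805 and 0.0793), arterial (0.102 and 0.103), fibroblast matrix (0.134 and 0.129) and leukocyte genes (0.0519 and 0.0518) were not called. Immediate-early genes (lower, 0.0233; adjusted p = 0.64 with an estimated correlation) and leukocyte genes (higher, 0.035; adjusted p = 0.743 with an estimated correlation) turned without NG2-cre replicate 1, to 0.47 and 0.0968. They were not called without LepR-cre replicate 2 (0.183 and 0.743). In NG2-cre replicate 1, S100a8 was at 49.2 RPKM and Ngp, chosen after its values were seen, at 9.65, both the lowest of the 8 libraries. Adjusted over the list alone, 3 arterial genes and 1 adipocyte lineage gene, Fabp4 (-2.82 ± 0.61), were lower, and 0 genes of the other 7 lists differed. Without NG2-cre replicate 1, 1 fibroblast matrix and 1 arterial gene were lower over all genes. Other settings ended calls too. Fibroblast matrix genes were not called with voom (0.194), the stricter filter (0.0791), no filter (0.0611) or a pseudocount of 0.1 (0.0555), arterial genes with voom (0.0783), no filter (0.0726) or that pseudocount (0.0599), and adipocyte lineage genes with voom (0.134), no filter (0.107) or the stricter one (0.0601). Chondrocyte genes were not called with voom (0.051), leukocyte genes with no filter (0.0516) or the Y-linked covariate (0.095), and immediate-early genes with that covariate (0.467). That covariate by construction leaves NG2-cre replicate 1 out here, so it repeats that omission. Without both libraries high in cartilage transcripts the calls ended of chondrocyte (0.747), CAR marker (0.411), adipocyte lineage and arterial (0.291 each), fibroblast matrix (0.247), Schwann cell (0.188) and sinusoidal genes (0.0712).

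The 10 lists that were not called between LepR-cre and NG2-cre cells had adjusted p of 0.0522 (Notch pathway), 0.0525 (megakaryocyte and oxidative phosphorylation), 0.0571 (Y-linked with Xist), 0.159 (ribosomal protein), 0.26 (receptors), 0.303 (erythroid and cell cycle), 0.468 (basement membrane) and 0.737 (niche factors). Adjusted over the list alone, 1 niche factor, 1 basement membrane gene and 2 receptors were lower. Notch pathway genes were called lower without NG2-cre replicate 2 (0.0204) or either Myh11-creER library (0.0343 and 0.0369), and megakaryocyte (0.028 and 0.00153) and oxidative phosphorylation genes (0.00151 and 0.0208) without LepR-cre replicate 1 or NG2-cre replicate 1. Niche factors had a median of 0.04 and a mean of -0.11, and basement membrane genes a median of 0.08 and a mean of -0.17, with both tests pointing down. For the arterial genes above, the median was 0.00 and the mean -0.32. Ribosomal protein genes went both ways: lower without LepR-cre replicate 1 (adjusted p = 5.2e-09) or NG2-cre replicate 1 (1.43e-05), and higher without LepR-cre replicate 2 (0.00748) or NG2-cre replicate 2 (0.0116). Y-linked genes with Xist were called lower without NG2-cre replicate 2 (8.94e-11, 2 genes lower over all genes), since Ddx3y was at 21.3 RPKM in NG2-cre replicate 1. They were also called with the replicate block (0.0468), its crossed form (0.0483) and quantile normalization (0.0462). Ddx3y was chosen after its values were seen. Other settings called Notch pathway genes lower (stricter filter 0.0113, pseudocount of 0.1 0.025, array weights 0.0403, median of ratios 0.0457) and megakaryocyte genes lower (Y-linked covariate 0.00157, no filter 0.0277, pseudocount of 0.1 0.0362, array weights 0.0489, without CD31 replicate 1 or 2 0.045 and 0.0455). Oxidative phosphorylation genes were called lower with quantile normalization (0.00215), the Y-linked covariate (0.0207), median of ratios (0.0413) or array weights (0.0489), and ribosomal protein genes with the Y-linked covariate (1.4e-05) or quantile normalization (0.0247). As the covariate by construction leaves NG2-cre replicate 1 out here, its calls repeat that omission. Without both libraries high in cartilage transcripts, Y-linked genes with Xist (6.17e-07) and Notch pathway genes (0.0188) were called lower and ribosomal protein genes higher (0.038).

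CD31+ cells carried the endothelial program and little of the stromal niche factors. Plvap, a protein of fenestrated endothelium, was at 1460 RPKM (mean, n = 2) against 0.953 in the 6 stromal libraries (log2 fold change 9.65 ± 0.19, SE, adjusted p = 8.19e-07). The VEGF receptor Kdr was at 847 against 0.751 (9.02 ± 0.26, 1.13e-06). All 23 pan-endothelial genes were higher, over all genes and when adjusted over the list alone (camera adjusted p = 5.96e-15; adjusted p = 0.267 with an estimated correlation). They included the tight junction gene Cldn5 (8.84 ± 0.32) and Mmrn2 (8.48 ± 0.33). Sinusoidal and venous genes were higher in 16 of 17, on both adjustments (camera adjusted p = 1.96e-09; adjusted p = 0.267 with an estimated correlation). Among them were the scavenger receptor Stab2 (8.47 ± 0.3), the VEGF receptor Flt4 (8.07 ± 0.21) and Ackr1 (8.82 ± 0.55), a chemokine receptor of venules. Cxcl12 was at 142 ± 90.1 RPKM (SD, n = 2) in CD31 against a stromal mean of 7260 (-5.44 ± 0.39, adjusted p = 2.76e-05), and Kitl at 7.68 ± 1.13 against 239 (-4.51 ± 0.19, 3.35e-06). Of 27 niche factors, 19 were lower and 5 higher, on both adjustments (camera adjusted p = 2.04e-05; adjusted p = 0.267 with an estimated correlation). The higher ones were E-selectin Sele (8.30 ± 0.29), the Notch ligands Dll4 (6.74 ± 0.21) and Dll1 (4.47), Tgfb1 (2.81) and Vcam1 (0.48). Dll1, Tgfb1 and Vcam1 were chosen after their values were seen, and the adjusted p of Vcam1, 0.0479, passed 0.05 without 6 of the libraries, to 0.306 without CD31 replicate 1.

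Stromal programs were lower in CD31+ cells. CAR markers were lower in 21 and higher in 4 of 26, on both adjustments (camera adjusted p = 8.61e-10; adjusted p = 0.267 with an estimated correlation). Among the lower ones were the platelet-derived growth factor receptor Pdgfrb (log2 fold change -7.36 ± 0.46) and Igfbp5 (-6.85 ± 0.35). Osteolineage genes were lower in 20 of 22, and in 21 when adjusted over the list alone (camera adjusted p = 1.04e-10; adjusted p = 0.267 with an estimated correlation), with the collagen Col1a2 (-7.47 ± 0.68) and the collagenase Mmp13 (-7.32 ± 0.52). Fibroblast matrix genes were lower in 12 and higher in 4 of 21, on both adjustments (camera adjusted p = 0.000517; adjusted p = 0.69 with an estimated correlation), with decorin Dcn (-6.96 ± 0.48) and Col3a1 (-6.90 ± 0.31). Contractile genes were lower in 23 of 24, on both adjustments (camera adjusted p = 3.6e-12; adjusted p = 0.447 with an estimated correlation), with the myosin light chain Myl9 (-6.51 ± 0.35). Pericyte markers were lower in 12 and higher in 7 of 20, on both adjustments (camera adjusted p = 0.00926; adjusted p = 0.865 with an estimated correlation). The Notch target Heyl (-6.55 ± 0.19) and Notch3 (-6.16 ± 0.33) were lower. The higher members included Kcnj8 (5.31) and Abcc9 (3.07), which form a potassium channel, and Mcam (2.67), chosen after their values were seen. The receptor list was lower in 9 and higher in 4 of 14, on both adjustments (camera adjusted p = 0.0409; adjusted p = 0.267 with an estimated correlation). The endothelin receptor Ednra (-6.29 ± 0.29) was lower and the natriuretic peptide receptor Npr1 (4.61 ± 0.26) higher. Without CD31 replicate 1, 0 CAR markers and 2 fibroblast matrix genes were higher, and without replicate 2, 2 of each. The pericyte call ended with voom (0.123), and the receptor call without NG2-cre replicate 1 (0.0503), with voom (0.145), after median-of-ratios (0.106) or quantile scaling (0.105), and with no filter (0.0637) or the stricter one (0.0501).

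Immediate-early and stress genes were higher in CD31+ cells in 13 and lower in 2 of 23, on both adjustments (camera adjusted p = 0.0232; adjusted p = 0.865 with an estimated correlation). Among the higher ones were the transcription factor Klf4 (log2 fold change 2.85 ± 0.27) and the phosphatase Dusp1 (2.48 ± 0.2). Lower genes numbered 1 without CD31 replicate 1 or 2, LepR-cre replicate 1 or Myh11-creER replicate 2. The list call ended without CD31 replicate 1 (0.112) or with a covariate for Y-linked transcripts (0.114). Ribosomal protein genes were higher in 13 of 35, on both adjustments (camera adjusted p = 0.00226; adjusted p = 0.876 with an estimated correlation), led by Rps3 (1.34 ± 0.17). Without CD31 replicate 1, 3 ribosomal protein genes were higher, without CD31 replicate 2, 4, and without NG2-cre replicate 2, 22. After median-of-ratios scaling 7 were higher, and the list call ended with quantile normalization (0.0554). Over all genes 3467 were higher and 2625 lower in CD31+ cells, and 1747 and 1515 of them by over 2-fold. Their 2 libraries did not overlap the 6 stromal ones in 49.1% of genes, where chance gives 7.1%. The other 13 lists were not called, with adjusted p from 0.0503 (chondrocyte) to 0.904 (arterial and adipocyte lineage). Counts higher and lower were 8 and 6 of 17 for arterial, 9 and 6 of 18 for Notch pathway, 7 and 6 of 15 for adipocyte lineage, 5 and 4 of 16 for basement membrane, 7 and 0 of 12 for megakaryocyte, 5 and 3 of 20 for interferon-stimulated and 1 and 4 of 9 for Schwann cell genes. They were 4 and 0 of 29 for oxidative phosphorylation (0 and 0 when adjusted over the list alone), 1 and 1 of 24 for cell cycle, 1 and 0 of 22 for leukocyte, 0 and 1 of 20 for chondrocyte, 1 and 0 of 11 for erythroid and 0 and 0 of 5 for Y-linked genes with Xist. These counts moved when single libraries were left out, and part of this may be lost power. Without CD31 replicate 1, 2 megakaryocyte, 3 interferon-stimulated, 0 oxidative phosphorylation and 0 erythroid genes were higher, and 2 Schwann cell, 0 interferon-stimulated, 0 cell cycle and 0 chondrocyte genes lower. Without replicate 2, 2 basement membrane, 3 interferon-stimulated, 1 oxidative phosphorylation and 0 Schwann cell, cell cycle and erythroid genes were higher, and 2 Schwann cell, 0 cell cycle and 0 chondrocyte genes lower. Without LepR-cre replicate 2, 3 megakaryocyte and 2 oxidative phosphorylation genes were higher, and 2 Schwann cell and 0 interferon-stimulated genes lower. Without LepR-cre replicate 1, 1 interferon-stimulated and 0 cell cycle genes were lower. Without Myh11-creER replicate 1, 11 cell cycle, 3 leukocyte and 2 Schwann cell genes were higher, and 6 interferon-stimulated and 3 chondrocyte genes lower. Without Myh11-creER replicate 2, 10 oxidative phosphorylation, 3 cell cycle and 2 leukocyte genes were higher, and 7 chondrocyte genes and 1 erythroid gene lower. The fit without NG2-cre replicate 1 had 4 Y-linked genes higher, and 1 Y-linked, 2 chondrocyte, 1 megakaryocyte, 1 interferon-stimulated and 0 cell cycle genes lower. Without NG2-cre replicate 2, 5 leukocyte, 3 Y-linked and 2 Schwann cell genes were higher, and 2 chondrocyte, 1 megakaryocyte and 1 interferon-stimulated gene lower. The test of oxidative phosphorylation genes pointed up, and down after median-of-ratios or quantile scaling. Some of these lists were called under other settings. Megakaryocyte genes were higher without CD31 replicate 2 (0.00415), Myh11-creER replicate 1 (0.0371) or NG2-cre replicate 2 (0.0438), without both libraries high in cartilage transcripts (0.033), after median-of-ratios (0.0281) or quantile scaling (0.0177), with no filter (0.0128) and with the Y-linked covariate (0.0194). Chondrocyte genes were lower without Myh11-creER replicate 2 (0.000605) or NG2-cre replicate 1 (0.00631), with the crossed replicate block (0.0175), with array weights (0.0238) and with a pseudocount of 0.1 (0.0441). Cell cycle genes were higher without Myh11-creER replicate 1 (0.0082) or both libraries high in cartilage transcripts (0.00352), and leukocyte genes without both (0.00138) or with the Y-linked covariate (0.0136). Signs of median, mean and test differed for adipocyte lineage (-0.10, 0.46, down), interferon-stimulated (-0.22, 0.08, down) and erythroid genes (-0.04, 0.05, down). Without CD31 replicate 1, 2287 genes were higher, and without replicate 2, 2190 were higher and 1730 lower. The median log2 fold change over all genes was 0.109, and -0.021 after median-of-ratios scaling. The balance of higher and lower calls, with 56.9% higher, therefore depends on the scaling.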

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

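Voom on recovered reads, the crossed replicate block, the covariate for Y-linked transcripts and the fit without both libraries high in cartilage transcripts were chosen after seeing the data; the cause of each change below was not tested unless stated. Between LepR-cre and NG2-cre, 0 genes higher and 0 lower became 2 lower with the filter at RPKM of 5, 1 lower with quantile normalization, 2 higher and 5 lower with array weights, 3 lower with the replicate block, and 2 higher and 44 lower with the Y-linked covariate, which by construction leaves NG2-cre replicate 1 out of this comparison. Without 1 library the counts ran from 0 to 2 higher and 0 to 44 lower, and called lists from 8 to 15. With an estimated correlation 0 lists were called in each of the 4 comparisons. The estimate lay above the preset of 0.01, which widens the test, for all lists but arterial (0.00336) and receptor genes (-0.0045). For these a larger correlation does not account for the change. With an estimate, camera also tests on the 4 residual degrees of freedom, which raises p-values. With the preset it tests on nearly as many as there are genes. For the receptor list in CD31 the camera adjusted p went from 0.0409 to 0.267. For LepR-cre against Myh11-creER, quantile normalization gave 1937 higher and 1326 lower (2457 shared in direction with the reported calls), the test against a 2-fold change 106 and 421 (a stricter hypothesis), the Y-linked covariate 430 and 903 (1174 shared), and the fit with the 2 compared groups alone 1218 lower (fewer samples). The Y-linked covariate ended the calls of Lepr (log2 fold change 2.35 to 2.63, adjusted p = 0.0578), Cxcl12 (2.57 to 3.21, 0.055), Il6 (-2.95 to -1.79, 0.076) and Il7 (2.66 to 2.32, 0.127); it rests on NG2-cre replicate 1 against 2, which also differ in cartilage, bone and granulocyte transcripts. Without 1 library the counts ran from 529 to 1084 higher and 918 to 2039 lower, with 8 to 12 lists. For NG2-cre against Myh11-creER, quantile normalization gave 1511 and 1102 (1944 shared), the 2-fold test 50 and 251, and the fit with the 2 compared groups alone 260 and 448; without 1 library they ran from 395 to 758 and 726 to 1650, with 9 to 13 lists. For CD31, the 2-fold test gave 993 and 886, and without 1 library they ran from 2190 to 3595 and 1730 to 2763, with 10 to 13 lists. Named genes that kept their calls without each library numbered 30 of 48, 38 of 59 and 50 of 52 in these 3 comparisons; a lone sample was assumed to vary like the other groups. Signs turned between LepR-cre and NG2-cre, in genes not past the threshold, with quantile normalization for Cxcl12 (0.00), Hp (0.10) and Fos (0.05). With the Y-linked covariate they turned for Hp (0.37), Col6a2 (-0.11), Mgp (-0.77), Tfpi (-0.01), S100a8 (-1.48), S100a9 (-1.52), Fos (0.19) and Junb (0.28). Without both libraries high in cartilage transcripts they turned for Cxcl12 (-0.18), Pdgfrb (-0.02), Col1a1 (0.31), Fbln5 (-0.08), Vcam1 (-0.04), S100b (-0.07) and Bst2 (0.31). Without 1 library these ran: Cxcl12 -0.18 to 0.46, Hp -0.39 to 0.37, Pdgfrb -0.02 to 0.61, Col1a1 -4.23 to 0.31, Col6a2 -0.11 to 0.51, Mgp -0.77 to 1.48, Fbln5 -0.08 to 0.19, Vcam1 -0.04 to 0.12, Tfpi -0.05 to 0.86, S100b -0.07 to 0.29, S100a8 -1.48 to 2.37, S100a9 -1.52 to 2.50, Fos -0.42 to 0.19, Junb -0.51 to 0.28, Bst2 -0.48 to 0.31, and Pecam1 in NG2-cre against Myh11-creER -1.48 to 0.27. Depth sets a floor of 0.023 to 0.0434 RPKM (3 reads in a gene of 2000 bases); whether depth or the spread between libraries limits the calls was not tested.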

Other observations

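The genes of this and the next paragraph, and all tests of the mural and cartilage patterns, were chosen after the values were seen; the tests of Nnt were written before their results. Of 14 neuropeptide, adrenergic and leptin receptors, 4 were higher and 5 lower in LepR-cre than in Myh11-creER cells, and the list was not called (adjusted p = 0.878). Among them, Myh11-creER cells had more transcript of the neuropeptide Y receptor Npy1r (log2 fold change of LepR-cre over Myh11-creER -5.37, adjusted p = 0.000212), the angiotensin receptor Agtr1a (-3.59, 0.000356) and the adrenergic receptor Adra1d (-1.30, 0.00409), while LepR-cre cells had more of the beta-adrenergic receptor Adrb3 (1.41, 0.00513) and the natriuretic peptide receptor Npr1 (1.82, 0.00637). Of 18 Notch pathway genes, 8 were higher and 1 lower in Myh11-creER cells and 9 were not past the threshold (list adjusted p = 0.375). The higher ones included the targets Hey2 (-4.22, 0.000341) and Nrarp (-3.93, 0.000231) and the receptor Notch3 (-2.47, 0.00507), and the Notch-modifying enzyme Lfng was the 1 higher in LepR-cre cells (2.76, 0.00025). Of 16 basement membrane genes, 2 were higher and 7 lower in LepR-cre cells (list not called, adjusted p = 0.413). Single members were Lama5 (-3.77, 0.000754), Lama2 (-2.33, 0.000994) and Lamb2 (-2.17, 0.000898), higher in Myh11-creER, and Lamb1 (1.32, 0.00219), higher in LepR-cre cells. Without LepR-cre replicate 1 or 2, 4 of the Notch pathway genes and 4 of the basement membrane genes were higher in Myh11-creER cells, while the single genes given here kept their calls without each library in turn.

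Arterial endothelial genes went both ways in CD31+ cells, with 8 higher and 6 lower of 17, and the list was not called (adjusted p = 0.904). Ly6c1 (log2 fold change 7.48, adjusted p = 2.39e-06), Sema3g (4.25, 5.05e-06) and the transcription factor Sox17 (3.25, 3.27e-06) were higher than in stromal cells, while Alpl (-5.02, 0.000105) and Fbln5 (-3.05, 1.83e-05) of the same list were lower. Adipocyte lineage genes also went both ways, with 7 higher and 6 lower of 15 (list not called, adjusted p = 0.904): Cd36 (6.92, 7.31e-06) and Fabp4 (5.94, 6.22e-05) were higher and Adipoq (-6.53, 2.62e-05) lower. Of 18 Notch pathway genes, 9 were higher and 6 lower (list not called, adjusted p = 0.43), with Mfng (6.65, 1.53e-06) and Notch4 (3.37, 9.13e-06) higher. The calls of these single genes held without each library in turn.

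NG2-cre libraries held mural transcripts at a low level, with Acta2 at 89.9 and 197 RPKM against 3580 in Myh11-creER and 2.56 in LepR-cre cells. If a share of mural cells were mixed with cells like the LepR-cre ones, each mural gene would imply the same share, but over 31 genes the upper quartile was 3.69 times the lower in replicate 1, above the bound of 3. In replicate 2 it was 2.11 times the lower, within that bound. The median NG2-cre to LepR-cre ratio of 26 CAR markers, 0.888, met its own bound. In a second test, set after that miss, 15 genes nearly silent in LepR-cre implied medians of 2.59% and 6.82% in replicates 1 and 2, with quartiles at most 1.29 times apart, so a share of mural cells may hold for these genes. Carry-over of Myh11-creER reads into every library alike was left open by a first test (median LepR-cre share 0.692 times that of NG2-cre replicate 1), but in a second test, also set later, 13 of the 31 genes in LepR-cre lay under 0.25 of the median share of NG2-cre replicate 1, which argues against it. Low mural transcription in every NG2-cre cell cannot be told apart from a share of mural cells (median share 6.64% in replicate 2), since libraries of pooled cells average over both.

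Cartilage transcripts stood high in 1 library each of Myh11-creER (replicate 1) and NG2-cre (replicate 2), led by Col2a1 at 2110 and 950 RPKM and Comp at 456 and 179. Of 20 chondrocyte genes, 19 in each group and 18 in both were at least 4 times higher than in the other replicate (median ratios 78.5 and 30.6), against 2 and 6 of 22 osteolineage genes, so cartilage cells in these 2 libraries are a candidate source. Leukocyte genes moved in the same libraries, with 15 and 19 of 22 and 13 in both at least 4 times higher (median ratios 4.56 and 5.33; S100a8 at 5980 against 1530 and 724 against 49.2 RPKM), in a comparison added later. In Myh11-creER alone 10 of 11 erythroid and 16 of 24 cell cycle genes did so too, against 1 of each in NG2-cre. Leukocyte and cartilage transcripts thus stood high together, and whether 1 common source such as the purity of the sort lies behind both was not tested. The chondrocyte list shares 0 genes with other lists, and 6 of its genes reach 1 RPKM in both LepR-cre libraries. Sorting against CD31, CD45 and TER119 would not remove cartilage cells. The gate on the Tomato reporter would remove those that the cre driver had not traced, so such cells would have to be traced or to have passed that gate. An exchange of the 2 libraries is argued against, since each correlated better with its own group by at least 0.0675, as is deeper sequencing (total reads at most 1.13 times apart within a pair). No biological explanation was tested, as the design gives none within a group.

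Nnt, a mitochondrial transhydrogenase on chromosome 13 (119335448 to 119408997), was at 24.9 to 29.8 RPKM in NG2-cre and Myh11-creER and at 6.60 to 8.86 in LepR-cre and CD31 libraries, a log2 ratio of 1.77. The strain C57BL/6J carries a deletion in Nnt, and a strain difference between the animals of the groups may apply. Its bound was met, as 7 expressed genes within 1 Mb had a median log2 ratio of 0.17 (-0.44 to 0.46). Level neighbours do not set a strain difference apart from other causes that act on Nnt alone. Lower mitochondrial gene expression as a whole is argued against by a median of 0.16 over 29 oxidative phosphorylation genes. A gap as large in that direction was seen in 144 genes (Nnt included), and in 20 the opposite way, so a gap of this size is not unusual by itself. How evenly values lie within each set of libraries was not counted. A difference between the cell types stays open, as untested.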
